A study of Homo sapiens with 4 samples.

How the data were processed

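RNA from LAPC-4, an established human prostate cancer cell line that carries a functional androgen receptor, was measured on 4 custom 1-colour (Cy3) oligonucleotide arrays for miRNAs. Per the labels' protocols, cells were kept in medium with charcoal-stripped serum, which removes steroids, before R1881 was added at 0.1, 1 or 10 nM or left out. R1881 (methyltrienolone) is a synthetic androgen that binds the androgen receptor. Each dose was measured on 1 array, and the length of exposure was not given in the sources used here. Total RNA was extracted with Trizol and labelled with Cy3, per the labels' protocols.

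For each array the authors deposited 1 intensity per probe, headed as a mean signal per the file headers. The values are multiples of fractions of a unit and most lie near a common floor, so they are averages over repeat spots without background subtraction. The spots themselves were not used here, so no spread between repeat spots could be given. The image software and the treatment of flagged spots were not given in the sources used here. Each array held 1406 probes. Of these, 455 were for human miRNAs and 604 were mismatch probes, copies of a probe that carry mutated bases. A value of 0 stood for a missing value and occurred in 28 mismatch probes on at least 1 array.

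The authors' deposited value table was compared with the scanner intensities of the same arrays. Each of its columns equalled the intensity minus a constant, which was 84.5 for the untreated array and 82, 87 and 76 at 0.1, 1 and 10 nM. These constants were the medians of the mismatch probes of each array with the 0 values included. Probes under about 2 times that constant were left blank. The column medians were 260.5, 226.2, 269 and 213.5 in order of dose. The series' design text says that data are relative to the untreated sample, but this table was on a linear scale, was not scaled between arrays and held no ratio. It was used as an alternative only, on its 74 human miRNAs with a value on every array.

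For the main values, 0 was set to missing, the background was corrected with normexp (offset 50, fitted on all spots), and log2 values were quantile normalized over all probes (R 4.3.3, limma 3.58.1). A probe was taken as detected on an array when its intensity lay above the 95th percentile of that array's mismatch probes. This threshold was 117.9 on the untreated array and 134.6, 137.9 and 143.8 in order of dose. The rule asked for negative control spots. The mismatch probes were chosen for this after the probe names had been seen, because the authors' background was their median and because the 7 probes named neg include Bio B and Bio C spikes with clear signal. Tests used the 136 human miRNA probes detected on at least 1 array, of which 106 were detected on all 4. Log2 folds are differences of normalized log2 intensity from the untreated array. Because of the offset, they understate changes of dim probes. Where a probe was above the threshold on only 1 side of a comparison, the fold is a bound ("at least N-fold"), taken against the higher of the dim probe's own value and the lowest value among detected probes of the dim array. Directions and counts by size use the measured folds of these probes.

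With 1 array per dose, no single dose could be tested against the untreated array, and detected miRNAs at least 1.5-fold from it were counted instead. The arrays' number limits the precision. A limma fit of log2 intensity on the dose level (0, 1, 2 or 3, in order of dose) gave the dose trend, and a second limma fit set the 3 treated arrays against the untreated one. Both were two-sided, with Benjamini-Hochberg adjustment and 2 residual degrees of freedom. In the trend, departures from a straight line count as error, and in the second fit differences between doses do. The lone untreated array is assumed to vary like the treated ones. No label says that the RNA came from separate cultures beyond the doses, so p-values measure only the spread between these arrays, which may be technical. Both fits were tested on simulated data drawn around the means of the 136 miRNAs, 40 of them changed. With a residual SD of 0.083 (log2), the dose trend recovered 99.4% of slopes of 0.2 per dose level. With a residual SD of 0.077, the treated fit recovered 99.9% of log2 folds of 0.5, each over 100 simulated sets. With 1 miRNA of no variance in the set, as miR-191 is after quantile normalization, these shares were 95.7% and 97.5%. The simulation gave every miRNA the same variance, which the real arrays do not have. These shares therefore do not tell how many such changes the fits would recover on the real arrays.

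A technical error was estimated from 23 detected mouse or rat probes that share a name with a detected human probe. The SD of 1 log2 fold from these pairs was 0.12 and that of a mean over the 3 doses 0.10. The SD of a list's median was simulated from that of 1 fold and lay between 0.041 for 12 detected members and 0.081 for 3.

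For each fixed list of miRNAs, the median log2 fold per dose was set among 10000 random lists of the same size, matched on mean level, which describes these arrays and is no test. The lists held androgen-induced and androgen-repressed miRNAs, seed families and genomic clusters (the miR-17-92 cluster and its paralogs, let-7, miR-200, miR-30, miR-15/16, miR-23/27/24, miR-29, miR-34, the miR-183 cluster and miR-99/let-7/miR-125) and miRNAs of prostate and other epithelia. Further lists held miRNAs of blood, muscle, nerve, liver, stroma and endothelium, and pluripotent cells, and the large chromosome 19 and chromosome 14 clusters. The named miRNAs were the 10 highest and 10 lowest by mean log2 fold among those on one side of 0 at all 3 doses, every detected member of both androgen lists, up to 10 past an adjusted p of 0.05 in the trend, and for other lists the members with the largest and smallest mean fold. Groups, tests, lists, naming rule and the first set of other settings were fixed before the data were examined. miR-21 was placed on the androgen-induced list from work that probably used these arrays, so its direction is not independent evidence.

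Other settings fixed at that time were no background correction, an offset of 16, median scaling, cyclic loess, no filter, detection on all 4 arrays, the deposited value table, a 2-fold size, other codings of dose, each treated array left out, and each treated array as the reference. Chosen after seeing the data were normexp fitted on the mismatch probes, detection at 2 times the mismatch median or above the neg probes, scaling to the Bio spikes, a match at least 1.5 times its mismatch, and the fits without miR-191. In the part on how the results depend on the processing, medians of lists are given relative to the median of all detected miRNAs. Elsewhere they are not, and they include the shift of all detected miRNAs under that scaling, unless stated otherwise. Names are those of the array's design. Of the 455 human probes, 433 matched a name or synonym of a miRNA gene in the RefSeq table of GRCh38.p14, which was used only for names and for which genes neighbour each other. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.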

Results

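The series measured miRNA levels in LAPC-4 prostate cancer cells that were untreated or had received R1881 at 0.1, 1 or 10 nM, with 1 array for each of the 4 conditions and no replicates. Human miRNAs above the mismatch background numbered 129 of 455 (28.4%) on the untreated array, 121 (26.6%) at 0.1 nM, 114 (25.1%) at 1 nM and 117 (25.7%) at 10 nM. The threshold was lowest on the untreated array and highest at 10 nM (143.8), so these counts do not show fewer miRNAs under R1881. The deposited table, cut at about 2 times the mismatch median, kept 75, 91, 85 and 111 human miRNAs in order of dose. miR-191 was the brightest human miRNA, with intensities of 4062, 3956, 3592 and 4606 in order of dose. Over the 136 detected miRNAs, log2 intensities correlated between arrays with r of 0.966 (untreated and 10 nM) to 0.992 (0.1 and 1 nM). These correlations are across miRNAs, which are not independent replicates.

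Before scaling, the Bio spike probes had higher signal on the treated arrays. The Bio B spike probe read 277.8 above the mismatch median on the untreated array and 391.2, 438 and 528.8 at 0.1, 1 and 10 nM, and the Bio C spike probe 444, 510.2, 521.5 and 698.5. In the same unscaled values, the median log2 fold of 74 human miRNAs was 0.14 at 0.1 nM, 0.19 at 1 nM and 0.50 at 10 nM. These 74 have a value on every array in the deposited table, and 75.7%, 64.9% and 90.5% of them lay above 0 in order of dose. Over all 455 human probes, most of them at background, the median intensity was 95.8 untreated and 93.8, 96.5 and 89.8 in order of dose. All folds below were taken after quantile normalization unless stated otherwise, so they are relative to the bulk of the probes.

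**Figure D1:**
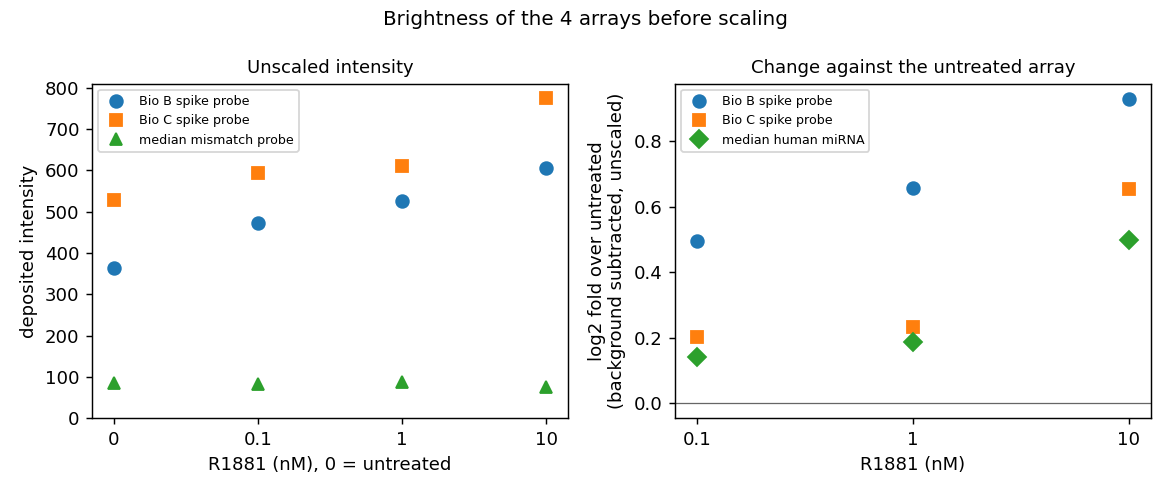
Left, deposited intensity (linear axis) of the Bio B and Bio C spike probes and of the median mismatch probe on the 4 arrays, by R1881 dose in nM. Right, log2 fold over the untreated array after subtraction of the mismatch median, without scaling, for both spikes and for the median of 74 human miRNAs; the median miRNA lies at 0.14, 0.19 and 0.50.

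The first comparison set each dose against the untreated array, to find miRNAs that respond to androgen. miR-99a and miR-125b, which are processed from neighbouring genes and are known to repress mTOR and p53 respectively, had the lowest mean folds over the 3 doses and the lowest folds at 1 and 10 nM; at 0.1 nM miR-663 was lowest. The log2 fold of miR-99a was -0.31 at 0.1 nM, -0.88 at 1 nM and -0.90 at 10 nM, and that of miR-125b was -0.27, -0.89 and -0.85. miR-211, encoded in an intron of the melanocyte gene TRPM1, and miR-568 had the highest measured mean folds. miR-568 lay 0.82, 0.66 and 0.80 above the untreated array (log2). miR-211 was above background only at 0.1 and 10 nM, where it was at least 1.06-fold and at least 1.19-fold higher. Its measured mean fold of 0.85 became 1.40 with an offset of 16 and, as a choice made after the data were seen, 0.47 with normexp on the mismatch probes. Under median scaling the mean folds of miR-99a and miR-125b were -0.38 and -0.44, against -0.70 and -0.67.

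By measured folds, 2 miRNAs were at least 1.5-fold higher at 0.1 nM, 3 at 1 nM and 3 at 10 nM. miR-568 and miR-211 were counted at all 3 doses, and miR-594 was the third at 1 and 10 nM, with log2 folds of 0.61 and 0.67. The place of miR-211 in these counts is uncertain, since its bounds at 0.1 and 10 nM lie under 1.5-fold and at 1 nM neither side was above background. Among miRNAs detected on all 4 arrays, 1 (miR-568) was at least 1.5-fold higher at 0.1 nM and at all 3 doses. At least 1.5-fold lower were 0 miRNAs at 0.1 nM, 3 at 1 nM (miR-99a, miR-125b and miR-192) and 3 at 10 nM (miR-99a, miR-125b and miR-663), and 0 were lower by this size at all 3 doses. Without the 0.1 nM array, 2 (miR-99a and miR-125b) were lower by this size at both remaining doses. These counts have no test, and the SD of 1 log2 fold between same-named probes was 0.12. With median scaling in place of quantile normalization, 40 miRNAs were at least 1.5-fold higher and 0 lower at 10 nM. That scaling levels the median of all probes, most of them at background, and changed the 10 nM folds little. For miR-99a the fold was -0.36, against -0.34 unscaled. The median of all detected miRNAs at 10 nM lay at 0.36 under it, and the 40 include this shift.

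Among the other low miRNAs, miR-192, which p53 is known to induce, had log2 folds of -0.26, -0.60 and -0.56. The folds of miR-30d were -0.38, -0.44 and -0.57. let-7a, of the family that represses RAS and HMGA2, had folds of -0.35, -0.45 and -0.56, although its unscaled intensity was 2384 untreated and 2208, 2020 and 2438 on the treated arrays and a mouse probe of the same name had folds of -0.17, -0.10 and -0.18. miR-663 had folds of -0.54 and -0.58 at 0.1 and 1 nM and was at least 1.57-fold lower at 10 nM, where it was not above background. miR-638 had folds of -0.46, -0.32 and -0.50. miR-375, known for its part in insulin secretion, was above background on the untreated array alone, where the threshold was lowest. It was at least 1.20-fold, 1.18-fold and 1.20-fold lower. miR-608 was likewise detected untreated alone, at least 1.19-fold, 1.17-fold and 1.19-fold lower, and miR-361 was at least 1.24-fold lower at 1 nM and 1.26-fold lower at 10 nM. Median scaling, under which the median of all detected miRNAs lay at 0.11, 0.13 and 0.36 in order of dose, brought these low mean folds nearer to 0. That of miR-192 was -0.22 in place of -0.47, that of miR-30d -0.16 in place of -0.47, that of let-7a -0.13 in place of -0.45 and that of miR-638 -0.16 in place of -0.43. The others became -0.39 (miR-663, from -0.63), -0.22 (miR-608, from -0.46), -0.15 (miR-375, from -0.40) and -0.16 (miR-361, from -0.39).

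Among the other high miRNAs, miR-16, which is known to repress BCL2, had a log2 fold of 0.35 at all 3 doses, and its unscaled intensity was 1880 untreated and 2667, 2854 and 3610 on the treated arrays. miR-594 had folds of 0.44, 0.61 and 0.67, and its name matched no gene of the RefSeq table. miR-575 had folds of 0.12, 0.48 and 0.52. miR-640, miR-326, miR-629 and miR-631 were above background on the 3 treated arrays and not on the untreated one. At 10 nM they were at least 1.42-fold, 1.20-fold, 1.31-fold and 1.12-fold higher. miR-647 was above background at 0.1 and 10 nM, at least 1.08-fold and 1.14-fold higher. Under median scaling the mean folds of miR-594, miR-629, miR-575 and miR-16 were 0.88, 0.63, 0.65 and 0.66, against 0.57, 0.41, 0.37 and 0.35, and that of miR-16 was 0.18 with scaling to the Bio spikes. The mismatch probe of miR-568 was brighter than its match on every array (288 against 133.5 untreated, 420 against 288.5 at 10 nM). At 10 nM the match of miR-647 was 0.84 times its mismatch, and that of miR-640 was 1.25 times.

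**Figure D2:**
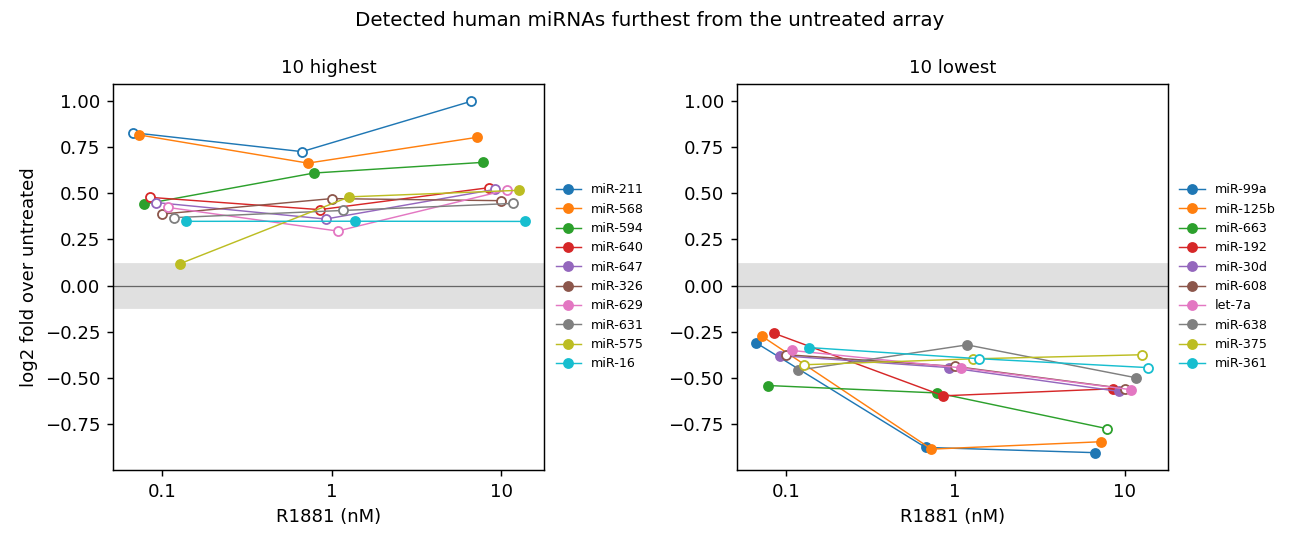
Log2 fold over the untreated array (vertical) against R1881 dose in nM (horizontal, evenly spaced, points shifted sideways for legibility) for the 10 miRNAs with the highest and the 10 with the lowest mean fold, 1 array per dose and no error bars. Open circles mark folds with a side not above background, and the grey band is 1 SD of a fold between same-named probes (0.12 either way); miR-99a reaches -0.90 and miR-125b -0.85 at 10 nM.

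The 3 folds of a miRNA share the untreated array. On one side of 0 at all 3 doses lay 72.1% of the detected miRNAs, where simulated unchanged arrays gave 49.9%. Across miRNAs, folds at 2 doses correlated with r of 0.84 (0.1 and 1 nM), 0.83 (0.1 and 10 nM) and 0.87 (1 and 10 nM), against 0.50 simulated. Their mean covariance was 0.062 against 0.0070 simulated, a difference of 0.055. Called at both 1 and 10 nM were 3 higher and 2 lower miRNAs, where independent lists would share 0.066 in each direction. Simulated unchanged arrays, which vary by the technical error alone and share the untreated one, gave 0. A call lies far beyond the SD of that error, so this 0 was bound to occur. The simulated 0.50 and 49.9% follow from the shared untreated array. The error comes from same-named probes on the same arrays, so differences between arrays or cultures that move both probes cancel in it. The excess over the simulation therefore cannot tell an effect of R1881 from such differences. Part of the excess may also come from the shared array, which cannot be split.

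The second comparison asked for a trend over the ordered doses. miR-99a had the steepest downward slope, -0.33 per dose level (SE 0.055, adjusted p = 0.121 by limma). miR-125b followed with -0.31 (SE 0.063), and miR-100, whose sequence is close to that of miR-99a so that their probes can share signal, had -0.20 (SE 0.034), each with the same adjusted p. Of the 136 miRNAs, 0 passed an adjusted p of 0.05 in limma, while 12 higher and 22 lower ones had an unadjusted p under 0.05. This count of 0 rests on 1 probe. miR-191 ranked first on every array, so quantile normalization gave it the same value on each and a variance of 0, which lowered the prior degrees of freedom from 9.7 to 2.54. Without miR-191, a choice made after the data were seen, 4 miRNAs rose with dose in limma's trend (miR-594, miR-211, miR-575 and miR-564) and 10 fell. The lower ones were miR-99a, miR-125b, miR-100, miR-663, miR-192, let-7a, miR-30d, miR-608, miR-30a-5p and let-7c, with adjusted p from 0.00412 for miR-99a to 0.0493 for let-7c. Over the settings run, other dose codings and left-out arrays included, the adjusted p in the trend ranged from 0.000114 to 0.598 for miR-99a and from 0.00672 to 0.985 for let-7c. miR-564 and miR-30a-5p are named here, and miR-99b and let-7d below, after their values were seen. Cyclic loess gave 10 higher and 13 lower, and the fit without the 10 nM array 8 higher and 4 lower. Median scaling, which keeps the upward shift of the detected miRNAs, gave 48 higher and 1 lower.

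The third comparison set the 3 treated arrays against the untreated one. The lowest adjusted p in limma was 0.0755, shared by miR-568 (log2 fold 0.76, SE 0.087), miR-211 (0.85, SE 0.13), miR-640 (0.47, SE 0.069), miR-326 (0.44, SE 0.060), miR-631 (0.41, SE 0.057), miR-16 (0.35, SE 0.045), miR-375 (-0.40, SE 0.051) and miR-31 (-0.35, SE 0.052). Each of these lay on one side of 0 on 3 of 3 treated arrays. For miR-211, miR-640, miR-326, miR-631 and miR-375 the bounds given above apply to the size. Of the 136 miRNAs, 0 passed an adjusted p of 0.05, and 16 higher and 25 lower ones had an unadjusted p under 0.05. With cyclic loess 9 higher and 8 lower passed, and with scaling to the Bio spikes, chosen after the data were seen, 8 and 19.

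Of the 7 androgen-repressed miRNAs on the array, 6 were detected, and all 6 had a mean log2 fold below 0; under median scaling, 1 of the 6 lay above 0. The list's median was -0.21 at 0.1 nM, -0.30 at 1 nM and -0.45 at 10 nM, at percentiles 3, 1.92 and 0.225 of random lists. It was -0.03, -0.12 and -0.02 under median scaling and 0.00 at 10 nM in the deposited table. The median of all detected miRNAs at 10 nM was 0.36 under median scaling and 0.50 in the deposited table. Relative to that median, the list stood at -0.39 and -0.50 at 10 nM, against -0.38 in the main values. miR-100 had log2 folds of -0.08, -0.40 and -0.57 and let-7c of -0.20, -0.20 and -0.50. miR-31 had folds of -0.31, -0.36 and -0.37. miR-222, which with miR-221 represses the cell cycle inhibitor p27, had a fold of -0.21 at 0.1 nM and was at least 1.17-fold and 1.19-fold lower at 1 and 10 nM, where it was not above background. miR-221 had folds of 0.01, 0.00 and -0.09. Under median scaling the mean folds of miR-100, let-7c, miR-31 and miR-222 were -0.11, -0.05, -0.06 and -0.03, against -0.35, -0.30, -0.35 and -0.28, and that of miR-221 was 0.22. In the dose trend 4 of the 6 fell when adjusted over the list alone (miR-99a, miR-100, let-7c and miR-222), and 0 when adjusted over all 136 miRNAs.

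Of the 14 androgen-induced miRNAs on the array, 10 were detected, with a median log2 fold of -0.04, 0.04 and 0.12 in order of dose, at percentiles 49.4, 85.1 and 92.1 of random lists. The median of the members' mean folds was 0.06, and -0.08 with scaling to the Bio spikes, 0.32 under median scaling and 0.43 in the deposited table. Relative to the median of all detected miRNAs, these were 0.11, 0.08, 0.14 and 0.15. Under median scaling the median of all detected miRNAs lay at 0.11, 0.13 and 0.36 in order of dose. The members' folds under that scaling include this shift. miR-21, which represses PDCD4, had folds of 0.22, 0.34 and 0.34; it was placed on the list from work that probably used these arrays. miR-148a had folds of 0.18, 0.41 and 0.18. miR-101, which represses EZH2, had folds of 0.06, 0.14 and 0.18, and miR-19a of 0.12, 0.15 and 0.06. miR-193a had folds of -0.30, 0.06 and 0.39. miR-23a (-0.23, -0.14 and -0.20), miR-27a (-0.06, -0.05 and -0.17) and miR-24 (-0.02, 0.02 and 0.20) had mean folds above 0 under median scaling (0.15, 0.14 and 0.32). miR-141 had folds of -0.20, -0.25 and -0.36, and miR-125b, also a member, was among the lowest of all. The mean folds of miR-21, miR-148a, miR-101, miR-19a and miR-193a were 0.60, 0.58, 0.37, 0.33 and 0.31 under median scaling, against 0.30, 0.26, 0.13, 0.11 and 0.05, and that of miR-141 was -0.07 against -0.27. In the trend 0 members passed limma's adjusted p of 0.05, both over all miRNAs and adjusted over the list alone.

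**Figure D3:**
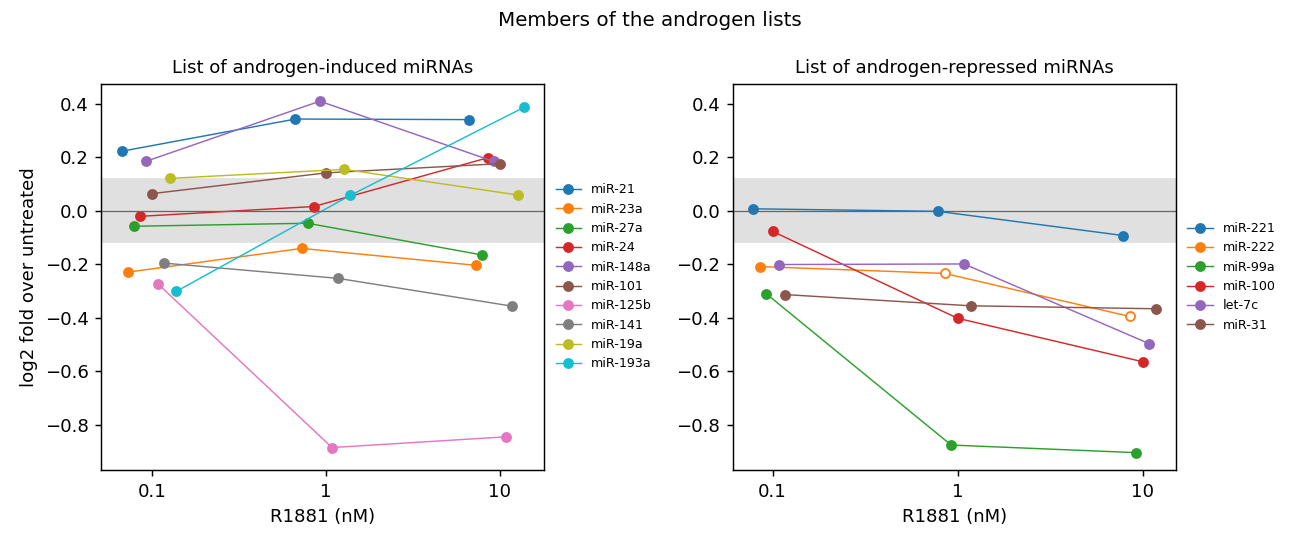
Log2 fold over the untreated array (vertical) against R1881 dose in nM (horizontal, evenly spaced, points shifted sideways) for the 10 detected members of the androgen-induced list and the 6 of the androgen-repressed list, 1 array per dose and no error bars. Open circles mark folds with a side not above background and the grey band is 1 SD of a fold between same-named probes; at 10 nM the medians are 0.12 and -0.45.

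The miR-99/let-7/miR-125 list, which shares miR-99a, miR-100 and let-7c with the androgen-repressed list, had the lowest percentiles. All 7 of its members had a mean log2 fold below 0, although 2 of the 7 lay above 0 under median scaling. Members of close sequence, such as miR-99a and miR-100, can share signal, so the 7 are not independent readings. The random lists do not allow for this. The median was -0.20, -0.38 and -0.50 in order of dose (percentiles 1.98, 0.095 and 0.075). It was -0.06, -0.20 and -0.02 under median scaling and 0.00 at 10 nM in the deposited table. At 10 nM the median of all detected miRNAs was 0.36 under median scaling and 0.50 in the deposited table. In the trend 4 of the 7 (miR-99a, miR-125b, miR-100 and let-7c) fell when adjusted over the list alone and 0 over all miRNAs. In the RefSeq table the gene of miR-99a stands next to that of let-7c and then a miR-125b gene. The gene of miR-99b stands next to that of let-7e and then that of miR-125a. miR-99b had folds of -0.31, -0.38 and -0.31 and miR-125a, the member nearest 0, of -0.12, -0.18 and -0.17.

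The let-7 family had medians of -0.17, -0.12 and -0.26 (percentiles 2.73, 19.8 and 1.67). They turned to 0.07, 0.04 and 0.12 under median scaling, where the median of all detected miRNAs was 0.11, 0.13 and 0.36. Of its 9 detected members, 2 had a mean fold above 0, let-7d (0.10 at each dose) and miR-98 (0.15, 0.45 and -0.26). Its probes differ by few bases and can share signal. The miR-30 family had medians of -0.14, -0.14 and -0.31 (percentile 4.28 at 10 nM), from miR-30d and miR-30a-5p (-0.30, -0.24 and -0.54) on one side to miR-30b (0.26, 0.00 and 0.04) on the other, and a median of 0.20 at 10 nM under median scaling. The 2 low members fell in the trend when adjusted over the list alone. The miR-29 family, known to repress collagens and DNA methyltransferases, had medians of 0.08, 0.30 and 0.15 (percentile 96.1 at 1 nM), with miR-29c at 0.17, 0.47 and 0.15 and miR-29a at 0.08, 0.30 and 0.03. Its medians were 0.26, 0.41 and 0.70 under median scaling and 0.03, 0.12 and 0.08 with scaling to the Bio spikes.

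The epithelial miR-200 family, which represses ZEB1 and ZEB2, had 3 of 5 probes detected and a median of -0.22 at 10 nM (percentile 18.1; 0.15 under median scaling). In the trend 1 of the 3, miR-141, fell when adjusted over the list alone, and miR-200b had folds of -0.10, 0.01 and -0.22. Medians at 10 nM were 0.08 for the miR-17-92 list (percentile 91.0, 12 detected, miR-19b highest at 0.25, 0.52 and 0.06 and miR-92 lowest at -0.12, 0.01 and -0.10) and -0.07 for miR-15/16 (percentile 39.3, 5 detected, miR-195 lowest at -0.25, -0.14 and -0.39). They were -0.17 for miR-23/27/24 (percentile 20.6, 5 detected, miR-23b lowest at -0.14, -0.28 and -0.20), 0.00 for the miR-183 cluster (percentile 49.1, 3 detected, from miR-182 at -0.13, -0.32 and 0.00 to miR-183 at 0.00, 0.01 and 0.20) and -0.28 for the prostate and epithelial list (percentile 7.13, 4 detected). Under median scaling these medians lay above 0 at 10 nM for all 5 lists, where the median of all detected miRNAs was 0.36. That of miR-17-92 was 0.56 and that of the prostate and epithelial list 0.19. The miR-34 family had 0 of 3 probes detected.

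miRNAs of other cell types were mostly at background. Of 7 blood cell miRNAs 1 was detected, miR-155, with a fold of -0.04 at 0.1 nM and no signal above background at 1 and 10 nM. Of 5 muscle miRNAs 1 was detected, miR-206 (0.01, 0.04 and -0.10). Of 6 neural ones 2 were, miR-128a (0.05, 0.04 and 0.03) and miR-128b (0.12, 0.01 and 0.05). Of 7 stromal and endothelial ones 2 were, miR-126 (-0.04, -0.13 and -0.19) and miR-214 (0.21, 0.21 and 0.33). Detected were 0 of 1 liver, 0 of 8 pluripotent cell and 0 of 38 chromosome 19 cluster probes. Of 39 chromosome 14 cluster probes 4 were detected, with a median of -0.13 at 10 nM (percentile 38.9), among them miR-494 (0.03, 0.00 and -0.01) and miR-432 (0.01 at 1 nM, and not above background at 0.1 and 10 nM). Under median scaling the cluster's median at 10 nM was 0.21, against 0.36 for all detected miRNAs.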

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

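All tests in this part were chosen after the results had been seen. Among the probes for miRNAs without a human namesake, the probe for viral miR-K12-3 of Kaposi's sarcoma herpesvirus had a signal above the untreated array, with a mean log2 fold of 0.66 over the 3 doses and intensities of 212.2 untreated and 342.5, 382.5 and 462.8 on the treated arrays. The probe for mouse miR-713 had a mean log2 fold of 0.73, with intensities of 154 untreated and 257.2, 269.2 and 325.8. No human miRNA of either name is on the array, and both probes lie outside the comparisons of the report.

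The 10 highest human miRNA probes lay above the untreated array at all 3 doses, with a median mean log2 fold of 0.44, while 6 of the 10 were not above background on the untreated array. Binding that ignores the probe's sequence would add the same signal to a mismatch probe as to its match. At the 7 probes at least 1.5 times their mismatch at 10 nM, the mismatch fell short of the log2 fold this would give. The median shortfall was 0.65 (SD of such a difference 0.15). The 7 were picked by a ratio on a treated array, which itself favours a shortfall, so this median decides nothing for them as a set. Of the 7, miR-16, miR-594 and miR-575 were above background on every array, with normalized shortfalls of 3.43, 1.48 and 0.29. Such binding is argued against for miR-16 and miR-594. It stays open for miR-575, whose mismatch had a mean log2 fold of 0.34 against 0.37. For the 3 probes under that ratio (miR-568, miR-640 and miR-647) the median shortfall was 0.21 unscaled and 0.29 normalized, which leaves it open. Scaling to the Bio spikes left the median mean fold of the 10 at 0.49, while it put the median of all detected miRNAs at -0.15. The 10 were picked as the highest on these same arrays, which itself favours a median above 0 under another scaling. This value therefore decides nothing about the brightness of the arrays as a cause. The 2 spikes themselves differed, with mean log2 folds of 0.34 (Bio B) and 0.07 (Bio C) after quantile normalization. Bio B thus rose about as much as miR-16, the lowest of the 10 at 0.35 (0.18 with spike scaling). For miR-16 as well, brightness stays open. Other RNA of the extract that binds by sequence stays open: of 38 detected probes without a human namesake, those for miR-K12-3 and miR-713 included, 10.5% (exact 95% interval 2.94 to 24.8) lay as high as the 10th human miRNA, against 7.35% of human ones, and even 0 of 38 would have allowed up to 9.25%. A response to R1881 is the biological explanation in the design and may hold as well, and these arrays do not tell it from such RNA.

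miR-99a and miR-125b were lower at 1 and 10 nM. If the scaling between arrays had made this, some scaling should bring a fold to 0 or above, but the highest of the 4 folds over all scalings, the unscaled values included, was -0.34, against an SD of 0.12 for 1 fold. A defect of the miR-99a spots is argued against by the separate mouse probe of that name, with a mean log2 fold of -0.68 at 1 and 10 nM. Signal shared with miR-100 or other close sequences was not tested. A response to R1881 is a hypothesis that stays open, and with 1 culture per dose it may also be a difference between cultures.

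Before scaling, the Bio spike probes and most of the 74 human miRNAs with a value throughout the deposited table were brighter on the treated arrays (75.7%, 64.9% and 90.5% of the 74 in order of dose). Brighter labelling or scanning could account for this, since the spikes had a mean log2 fold of 0.79 at 10 nM against 0.50 for the median of these miRNAs. This assumes that equal amounts of spike RNA were added to each sample, so that their signal does not depend on the cells. The assumption was not tested. A single factor for all intensity, background included, is argued against at 10 nM. There the mismatch median was lower (log2 change -0.15) and lay 0.70 below the fold of the spike with the smaller fold, without subtraction. Such a factor stays open at 0.1 and 1 nM, where the mismatch median changed by -0.043 and 0.050. The smallest such gap there was 0.15, against an SD of 0.12 for 1 fold. Since the mismatch median is taken as the background, it cannot decide about 1 factor for the labelled signal above it. A change in the amount of miRNA per cell stays open as untested, and the point at which the spikes were added was not given in the sources used here.

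With the arrays put in other orders, the trend gave 34 miRNAs at an unadjusted p under 0.05 for the real order and at most 21 for the others, so 1 of 12 orders reached the real count. With each array in turn set against the other 3, the untreated one gave 41 and the others at most 3, so 1 of 4 choices did. Both sets are too few for a share under 0.05.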

How the results depend on the processing

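The alternatives named here as added, and no others, were chosen after seeing the data. The 10 highest and 10 lowest miRNAs kept the sign of their mean fold under each alternative that gave them a value; miR-99a ranged from -0.89 to -0.38 and miR-125b from -0.89 to -0.44. The other low ones came as near to 0 as -0.39 (miR-663), -0.22 (miR-192 and miR-608), -0.16 (miR-30d, miR-638 and miR-361), -0.15 (miR-375) and -0.11 (let-7a), where the SD of such a mean is 0.10, and the high ones as near as 0.18 (miR-16). Of the smaller mean folds, those of miR-23a, miR-27a, miR-24, miR-193a and miR-221 changed sign under at least 1 alternative. Of the mean folds of named miRNAs under the alternatives, 383 moved by less than 1 SD of such a mean and 95 by more. Alternatives that only change which miRNAs enter (other filters, no filter, and leaving out miR-191) cannot move a mean fold. They stand among the 383, so that count and the kept signs overstate how stable the folds are. The 10 highest and 10 lowest were also picked as extremes on one side of 0 on these same arrays. That choice itself favours a kept sign. Of the medians of lists other than the androgen lists, 315 moved by less than 1 SD of the list's median and 72 by more. The median log2 fold of all detected miRNAs was 0.11, 0.13 and 0.36 in order of dose under median scaling, 0.14, 0.19 and 0.50 in the deposited table and -0.12, -0.16 and -0.18 with spike scaling, against -0.06, -0.02 and -0.07, so signs of small folds depend on the scaling. At 10 nM, 50% of the miRNAs at least 1.5-fold away were higher, but 100% under median scaling and in the deposited table, 66.7% without a filter, 33.3% with normexp on the mismatch probes, 22.2% with spike scaling and 0% (0 of 1) with the neg filter. Of the 136 tested miRNAs, 30 were not above background on every array, so that some of their folds are bounds or cannot be given. The median of repeat spots was not run, since the intensities are means. No paired analysis was possible because each condition has 1 array and shares no replicate.

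Counts at least 1.5-fold away are given as higher and lower at 0.1, 1 and 10 nM, where the main counts were 2 and 0, 3 and 3, and 3 and 3, with 2 and 0 at all 3 doses. An offset of 16 gave 5 and 2, 6 and 6, and 9 and 10, with 1 lower at all 3. Median scaling gave 5, 7 and 40 higher and 0 lower at 10 nM, and in the deposited table there were 9 higher at 1 nM, 33 higher at 10 nM and 0 lower at 10 nM. Without a filter 6 were higher at 10 nM, and with detection on all 4 arrays 1 was higher at 0.1 nM and 1 at all 3. A 2-fold size left 0 in every count. With another array as reference, 0 were higher at all 3 comparisons for each of 0.1, 1 and 10 nM. Leaving out each treated array gave 0 to 2 lower at the remaining doses, the 2 without the 0.1 nM array, and 2 to 3 higher. Of the added alternatives, normexp on the mismatch probes gave 1 higher and 1 lower at 0.1 nM, 8 lower at 10 nM, and 1 higher and 1 lower at all 3. The neg filter gave 0 higher at each dose and at all 3, and 1 lower at 1 nM and at 10 nM. Spike scaling gave 1, 10 and 14 lower in order of dose and 1 lower at all 3. A match of at least 1.5 times its mismatch left 1 higher at 0.1 nM and 1 at all 3, which is miR-211. Detection on all 4 arrays left miR-568 instead, so no miRNA higher at all 3 doses passed both filters.

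In limma's dose trend, 0 higher and 0 lower became 48 and 1 with median scaling, 10 and 13 with cyclic loess, 7 and 11 without a filter, 31 and 1 in the deposited table and, as added alternatives, 5 and 25 with spike scaling and 4 and 10 without miR-191. Leaving out each treated array gave 0 to 8 higher and 0 to 4 lower, the 8 and 4 without the 10 nM array. Treated against untreated, 0 and 0 became 4 higher with median scaling, 9 and 8 with cyclic loess, 1 higher in the deposited table and, as added alternatives, 8 and 19 with spike scaling and 1 higher with the neg filter. The adjusted p of miR-99a ranged from 0.000114 to 0.598 in the trend. Relative to the median of all detected miRNAs, the androgen-induced list stood at 0.02, 0.06 and 0.19 in order of dose. It moved to 0.074 at 0.1 nM without a filter, to 0.11 at 1 nM and 0.35 at 10 nM in the deposited table, and at 10 nM to 0.14 with median scaling and 0.12 with detection on all 4 arrays. With the added neg filter it was 0.22 at 0.1 nM and 0.35 at 1 nM, and with the added detection at 2 times the mismatch median it lay on the other side of 0 at 0.1 nM (-0.029). The androgen-repressed list stood at -0.27 at 1 nM and -0.38 at 10 nM. These became -0.35 and -0.47 with an offset of 16, -0.35 and -0.49 with detection on all 4 arrays, -0.42 and -0.50 in the deposited table and, as added alternatives, -0.35 and -0.50 with detection at 2 times the mismatch median and -0.34 and -0.46 with a match of at least 1.5 times its mismatch. Without a filter the value at 1 nM was -0.20. The cause was not tested for any of these, except that fewer miRNAs enter under a stricter filter and that miR-191 has no variance after quantile normalization. Counts of higher miRNAs under median scaling and in the deposited table include the upward shift of all detected miRNAs given above.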

Other observations

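The values in this part were chosen after they had been seen, and none was tested. The probe for the start of the glycine tRNA, a small RNA that is not a miRNA, had log2 folds over the untreated array of 0.46, 0.65 and 0.35 in order of dose, with an intensity of 240 untreated. A second probe near the same end of that tRNA was above background on the 3 treated arrays and not on the untreated one. Probes for other parts of the glycine tRNA and for the lysine tRNA were not above background on any array. The mouse miR-709 probe had log2 folds of 0.45, 0.49 and 0.60, with intensities of 394.5 untreated and 805.2 at 10 nM. The probe for U6, a small nuclear RNA often used as a reference, was not above background on any array.

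Same-named probes of other organisms gave a second reading of some miRNAs. Mouse miR-99a had log2 folds of -0.27, -0.63 and -0.72, against -0.31, -0.88 and -0.90 for the human probe in the first comparison. Of the 23 pairs, 21 had mean folds on the same side of 0, and the largest difference between the folds of a pair was 0.58.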
